A study of Mus musculus with 6 samples.

How the data were processed

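Liver RNA of 8-week-old male C57BL/6 mice was measured on Clariom S mouse arrays, which carry short oligonucleotide probes summarised into transcript clusters, about 1 per gene. The 6 samples were 3 livers labelled WT and 3 labelled HMGB2-KO, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, and fragmented cDNA was amplified and labelled with biotin. The summarisation, background correction, normalization, software and gene annotation behind the values are not given in the sources used here.

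The deposited values were taken as log2 expression per transcript cluster. They run from -8.6 to 6.93 and scatter around 0, so a per-cluster baseline had been subtracted before deposition. The base of the logarithm is not given in the sources used here, and fold sizes hold only if it is 2. The baseline was not the median of these 6 arrays alone, and the arrays behind it were not analysed here. The absolute brightness of a cluster is therefore unknown, signal over background cannot be given, and no cluster's level was set against another's. The series held 2 deposited tables of these log2 values, and the largest difference between them was 0.

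Of 22206 clusters, 21371 carried 1 gene symbol, 832 carried several and 3 carried none. Genes were named only from clusters with 1 symbol. Neighbouring genes were taken from a RefSeq table of assembly GRCm38.p6, which held the symbol of 19889 of those 21371 clusters. The build used for the array annotation is not given in the sources used here, so no coordinates are printed.

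HMGB2-KO was compared with WT in limma 3.58.1 under R 4.3.3, with lmFit and eBayes at default settings on the deposited values, genotype as the only term, two-sided tests and Benjamini-Hochberg adjustment over all clusters at 0.05. A looser count took clusters with an unadjusted p under 0.05 and a log2 difference of at least 1 in either direction. The 42 gene lists of pathways and cell types were tested with camera, which compares a list with all other clusters, at a preset inter-gene correlation of 0.01, with adjustment over the lists. A list that camera called higher or lower stood so against the other clusters, whichever way its own values moved. Members were matched by exact symbol, which placed 906 of 965 list entries, and genes found only on clusters with several symbols were left out. For a symbol on more than 1 cluster, the cluster with the highest mean entered the list test. With centred values that choice does not pick the brightest cluster.

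The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Hmgb2 and, per direction, the 12 genes with the largest difference among clusters past the threshold with non-overlapping groups. Where fewer passed, the places went to the smallest unadjusted p under 0.05 among clusters without overlap, to be given as values. Predicted genes and olfactory, vomeronasal and taste receptor genes were counted but not named. For each list described, the 3 members with the smallest p were open to naming, and not all of these are reported here. The lists described at length were the 11 past the set test and 9 others, picked after the set tests were seen.

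The median cluster differed by -0.12 between HMGB2-KO and WT on the log2 scale, and centring each array on its median brought this to -0.01. Differences are therefore given relative to the median cluster, which places each 0.12 above its value as deposited. Most of that offset came with WT replicate 2, without which the median cluster differed by -0.04. That array was not raised alike in all clusters. For clusters it did not raise, the shift can overstate a higher difference and understate a lower one. Standard errors, p-values and the 2-fold rule were left as fitted on the deposited values.

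The test was checked on 20 simulated datasets of 22206 clusters with this design, each with 200 changed clusters. Of 1000 changes of each size, 38.2% were recovered at a log2 change of 1, 92.7% at 2, 97.8% at 3 and 99.1% at 4. Of the calls made, 5.14% were unchanged clusters. These shares hold for 200 changes together, and fewer true changes would be harder to call. The set test called 0 of 840 unchanged lists whose members varied independently, and in 20 of 20 simulations it called a list shifted by 0.5. The lists called in the real data had medians of 0.09 to 0.18, so that shift does not give the power at such sizes. The simulated noise was independent and held no array that stood apart, unlike the real arrays, so these shares may not carry over.

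Alternatives were a replicate block, the other deposited table, quantile normalization, centred arrays, filters on the mean value, a trended robust variance, array weights (statmod 1.5.0), an ordinary two-sample test, an adjusted threshold of 0.1, and each sample left out in turn. List tests also used an estimated correlation, fry and the mean of a symbol's clusters. With an estimated correlation, camera also uses the residual degrees of freedom of the 6 arrays, which it does not at the preset. Fry tests a list by itself, without comparing it with other clusters. A pseudocount was not needed on log values.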

Results

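The arrays compared liver expression between mice without HMGB2 and WT mice, and the stated aim was to screen for genes related to HMGB2, a high mobility group box protein that binds and bends DNA. Livers of 3 WT and 3 HMGB2-KO males aged 8 weeks gave values for 22206 transcript clusters. The labels call each sample a mouse liver and do not state that each came from a separate animal. P-values therefore measure only the spread between these samples, part of which may be technical. Clock genes argue against technical repeats of one liver within a genotype. The clock gene Dbp was 3.66, 5.24 and 0.05 in WT and 4.38, 5.50 and 0.06 in HMGB2-KO. Over 21 clock genes such deviations matched between samples of one number, with correlations of at least 0.93. One array stood apart. WT replicate 2 had a median of 0.26 on the log2 scale against 0.01 in WT replicate 1, -0.04 in WT replicate 3, and -0.04, -0.05 and -0.05 in the 3 HMGB2-KO arrays. It held the highest of the 6 values in 60.1% of clusters. The precision is limited by the number of arrays, and an exact permutation test of 3 against 3 cannot give a two-sided p below 0.1.

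Hmgb2 itself was lower in each HMGB2-KO liver than in each WT liver. Its values were 0.48, 0.62 and 0.38 in WT and -0.70, -0.38 and -0.48 in HMGB2-KO. Group means were 0.49 ± 0.12 (SD, n = 3) and -0.52 ± 0.17 (SD, n = 3). Relative to the median cluster the difference was -0.89 (SE 0.15), or 1.85-fold. As deposited it was -1.01. The limma adjusted p was 0.469, so the targeted gene did not pass the threshold over all clusters. Where its probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside that part would not check the labels.

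No gene passed the threshold between HMGB2-KO and WT liver. The smallest p among named genes belonged to lower values of Rgs21, of 2 cytochrome P450 genes, Cyp2c40 and Cyp2c67, of Hmgb2, and of Kif11, the kinesin that separates spindle poles in mitosis. Among higher values the smallest p was that of Ces2b, a carboxylesterase that hydrolyses lipid esters. With limma, 0 of 22206 clusters had an adjusted p under 0.05 and 0 had one under 0.1, and the smallest adjusted p was 0.403. At an unadjusted p under 0.05 there were 1092 clusters (4.92%), 16 higher and 1076 lower. That count was 2125 without WT replicate 3, 720 without HMGB2-KO replicate 2, 763 without WT replicate 2 (213 higher and 550 lower) and 2958 with array weights (458 higher and 2500 lower). With each array centred on its median it was 229 higher and 621 lower, and with quantile normalization it was 328 higher and 523 lower. An ordinary two-sample test with equal variances gave 0 clusters after adjustment and 1085 before it. The fit with array weights called 6 clusters, all lower. They were Rgs21, the receptor genes Vmn1r47, Vmn1r168 and Olfr890, and the 2 unnamed transcripts A530053G22Rik and 2310057J18Rik, and apart from Rgs21 they were named after their values were seen. The groups did not overlap in 2587 clusters, or 11.7%, where chance gives 10%.

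The looser rule, an unadjusted p under 0.05 with at least a 2-fold difference, took 68 clusters, 3 higher and 65 lower. With array weights it took 133, of which 63 were higher and 70 lower, so that balance depended on the weights. The count was 42 without WT replicate 2 (12 higher and 30 lower), 148 without WT replicate 1 (25 higher and 123 lower), 181 without WT replicate 3 and 105 without HMGB2-KO replicate 3. With centred arrays it was 40, of which 3 were higher and 37 lower.

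Of the genes named for higher values in every HMGB2-KO liver, Ces2b had the largest difference, 1.74 (SE 0.39), or 3.33-fold, with 0.62 ± 0.36 in WT and 2.24 ± 0.82 in HMGB2-KO (SD, n = 3). Dio1, the deiodinase that activates thyroid hormone in liver, differed by 0.63 (SE 0.16). Spp1, the secreted protein osteopontin, differed by 0.67 (SE 0.20), and Pecam1, an adhesion molecule of endothelial cells, by 0.55 (SE 0.17). Gpr1 differed by 1.34 (SE 0.42), or 0.45 with array weights, with WT values of -0.11, -1.82 and -1.72. The remaining genes named by the rule, with differences from 0.49 to 0.69, were Rnase13, Zfp280d, Pik3c2g, Prg4, Efemp1, Pnn and Ost4. All 12 had a limma adjusted p of 0.852.

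Of the genes named for lower values in every HMGB2-KO liver, Cyp2c40 differed by -1.39 (SE 0.21), or 2.63-fold, with 1.27 ± 0.04 in WT and -0.24 ± 0.42 in HMGB2-KO (SD, n = 3). Cyp2c67 differed by -0.99 (SE 0.17). Kif11 differed by -0.89 (SE 0.16), or -1.41 with quantile normalization, and Cenpp, a centromere protein, by -0.83 (SE 0.19). Rgs21, a regulator of G protein signalling, differed by -1.83 (SE 0.27), and Speer2 by -1.57 (SE 0.34). The differences of Erdr1, Ndst3, Brs3, Cdh26 and Henmt1 lay between -0.86 and -0.57. The limma adjusted p was 0.403 for Cyp2c40 and Rgs21, 0.537 for Cyp2c67 and Kif11, and 0.852 for the others. Hmgb2 was the remaining gene of the 12.

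**Figure D1:**
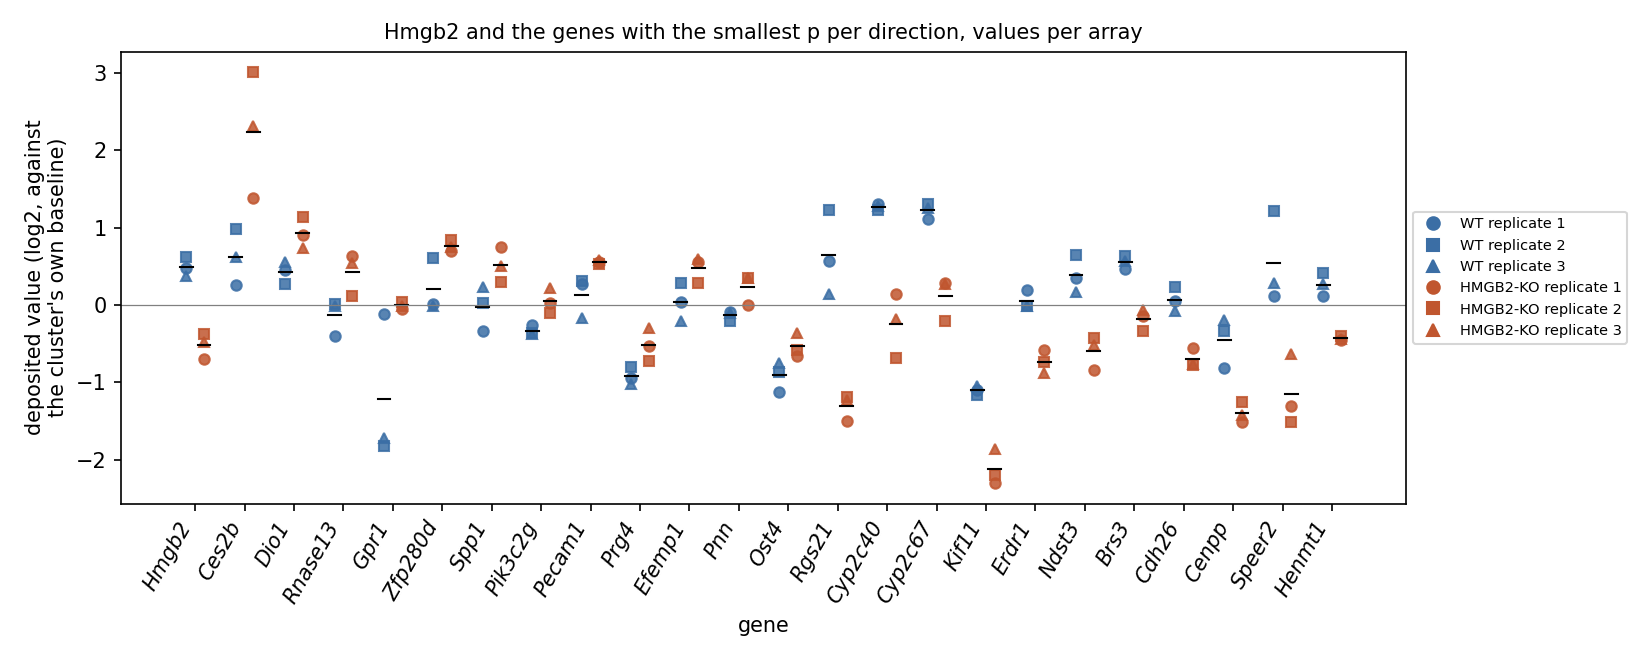
Deposited log2 values (vertical axis, against each cluster's own baseline) of Hmgb2 and the genes named in each direction (horizontal axis), with WT in blue, HMGB2-KO in orange, a marker shape per replicate number and a black line at each group mean. Ces2b lies between 1.39 and 3.01 in HMGB2-KO and between 0.26 and 0.99 in WT, and Cyp2c40 lies between 1.23 and 1.31 in WT and between -0.69 and 0.14 in HMGB2-KO.

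Genes of lipid droplets, the structures named in the title of the series, did not pass as a list with all samples and clusters and genotype as the only term. Of 27 measured members, 19 lay above the median cluster and 8 below, with a median of 0.10 and a camera adjusted p of 0.0709. The list passed as higher without HMGB2-KO replicate 3 (adjusted p 0.0119) and among clusters with a mean value above the median (0.0327), and had an adjusted p of 0.96 with an estimated correlation. It also passed as higher with a replicate block (0.0416), but not with the block on centred arrays (0.0569). Plin2, which coats lipid droplets in hepatocytes, differed by 0.40 (SE 0.16), by 0.23 without WT replicate 2 and by 0.16 with array weights. As deposited, the Plin2 difference was 0.27. Cidea, a protein that promotes droplet fusion, differed by -0.54 (SE 0.17), or -0.345 with array weights. Fatty acid synthesis and esterification, with 24 members, had a median of 0.04 and an adjusted p of 0.337, and Scd1, the stearoyl-CoA desaturase, differed by -0.18 (SE 0.16), with values from -0.33 without WT replicate 2 to -0.04 without WT replicate 3. Cholesterol synthesis had 19 of 25 members below the median cluster, a median of -0.14 and an adjusted p of 0.622.

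The camera test placed 11 of 42 lists above the other clusters in HMGB2-KO and 0 below, although none of their members passed the threshold alone. As deposited, the medians of these 11 lists ran only from -0.0351 (fatty acid uptake) to 0.0566 (heat shock proteins). The calls therefore place the lists against other clusters and do not show that their typical member rose. All 11 calls were lost with an estimated correlation, where camera gave adjusted p = 0.96 for fatty acid oxidation and periportal hepatocytes and adjusted p = 0.914 for the other 9, and fry called 0 lists. Lipid handling was represented by 2 of them. Fatty acid oxidation and PPARA targets had 25 of 34 members above the median cluster (median 0.10, adjusted p 0.00893). Its member with the smallest p, Pex11a, was at 1.51 (SE 0.75), or 0.45 without WT replicate 2. The next members, Fgf21, a fasting hormone, and Acaa1a, were at -0.18 (SE 0.19) and -0.15 (SE 0.18). Fatty acid uptake and lipoproteins had 19 of 28 above it (median 0.09, adjusted p 0.0251), with Cd36, a fatty acid transporter, at 0.37 (SE 0.15) and Pltp, a phospholipid transfer protein, at -0.34 (SE 0.16). Glucose metabolism and fasting response had 18 of 26 above it (median 0.15, adjusted p 0.00347). Its members G6pc, the last enzyme of gluconeogenesis, and Irs2, an adaptor of the insulin receptor, differed by 0.59 (SE 0.26) and 0.46 (SE 0.15), and G6pc by 0.33 without HMGB2-KO replicate 1 and 0.29 with array weights. Pfkfb1, an enzyme that sets glycolytic flux, was at -0.21 (SE 0.27).

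The lists in this paragraph share that loss with an estimated correlation. Male-biased liver genes had 20 of 23 members above the median cluster (median 0.14, adjusted p 0.000413), Ces2b among them and Cyp4a12a at 0.40 (SE 0.14). The acute phase response had 26 of 28 above it (median 0.13, adjusted p 0.000617), with Steap4 at 0.61 (SE 0.31), or 0.27 without HMGB2-KO replicate 2, and Apcs at -0.25 (SE 0.34), or 0.15 without HMGB2-KO replicate 2. The interferon response had 29 of 34 (median 0.12, adjusted p 0.0127), although Ifi27l2a was at -0.46 (SE 0.23), or -0.21 with array weights. Heat shock proteins had 11 of 14 (median 0.18, adjusted p 0.00853), and ribosomal proteins had 22 of 26 (median 0.13, adjusted p 0.00853). The circadian clock had 15 of 21 (median 0.16, adjusted p 0.0122), periportal hepatocytes 10 of 17 (median 0.18, adjusted p 0.0383), and Kupffer cells and macrophages 14 of 17 (median 0.15, adjusted p 0.00893).

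Members with the smallest p did not all go with their list. Of the 33 members with the 3 smallest p in each of the 11 lists, 16 lay below the median cluster, and so did the first member of 7 lists. These 7 were Pltp, Ifi27l2a, Hspa1a at -0.20 (SE 0.16), Rpl8 at -0.09 (SE 0.13), Hlf at -0.22 (SE 0.26), Hal at -0.17 (SE 0.15) and Slc40a1 at -0.12 (SE 0.15). The second members of the clock and periportal lists, Rora at -0.09 (SE 0.18) and Arg1 at -0.10 (SE 0.19), lay below it too. The p-values were fitted on deposited values, where the median cluster was itself below 0, which ranks lower members first. Over the alternatives Pltp ran from -0.56 to -0.20, Hspa1a from -0.34 to -0.06, Rpl8 from -0.175 to -0.00474, Hlf from -0.34 to -0.02, Hal from -0.28 to -0.11 and Slc40a1 from -0.19 to -0.03. Rora ran from -0.17 to -0.03, Arg1 from -0.23 to -0.02, Fgf21 from -0.26 to -0.09, Acaa1a from -0.33 to -0.02 and Pfkfb1 from -0.40 to -0.05, and Apcs reached -0.64 with quantile normalization.

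In WT replicate 2 alone, values more than 2 below all 5 other arrays occurred in 1 member of fatty acid oxidation and PPARA targets, 2 of fatty acid uptake and lipoproteins and 1 of ribosomal proteins. Without WT replicate 2, 3 lists passed: glucose metabolism and fasting response (adjusted p 0.0249) and the acute phase response (adjusted p 0.0475) as higher, and cell cycle and mitosis (adjusted p 0.0277, but 0.96 with an estimated correlation and all samples) as lower. The other 9 of the 11 lists then had adjusted p from 0.067 to 0.928.

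Apart from male-biased liver genes, which had an adjusted p of 0.128 without WT replicate 2, each of the 11 lists also lost its call under a setting listed here. With centred arrays the circadian clock (adjusted p 0.292) and periportal hepatocytes (0.0845) no longer passed. With quantile normalization these 2 (0.438 and 0.108), the acute phase response (0.187), fatty acid oxidation (0.0924) and fatty acid uptake (0.0636) did not. Array weights lost fatty acid oxidation (0.605), fatty acid uptake (0.644), ribosomal proteins (0.302), periportal hepatocytes (0.177), and the circadian clock and heat shock proteins (0.0852 each). Among clusters with a mean value above the median, fatty acid uptake (0.0824) and heat shock proteins (0.202) did not pass. Among the 5552 clusters with the highest means, fatty acid uptake (0.613) and the circadian clock (0.0834) did not. Periportal hepatocytes had 0.0551 with a trended robust variance and 0.0534 without receptor clusters. Without WT replicate 1, the interferon response (0.315) and Kupffer cells (0.0884) did not pass. Without WT replicate 3, fatty acid oxidation (0.0702), periportal hepatocytes (0.29), and the clock and glucose lists (0.0516 each) did not. Without HMGB2-KO replicate 1 the same held for fatty acid oxidation (0.0544), fatty acid uptake (0.164), the interferon response (0.0634) and ribosomal proteins (0.142). Without HMGB2-KO replicate 2 it held for fatty acid oxidation (0.94), the clock (0.24) and periportal hepatocytes (0.495). Without HMGB2-KO replicate 3 it held for the acute phase response (0.501), the interferon response (0.065), heat shock proteins (0.783) and Kupffer cells (0.228).

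**Figure D2:**
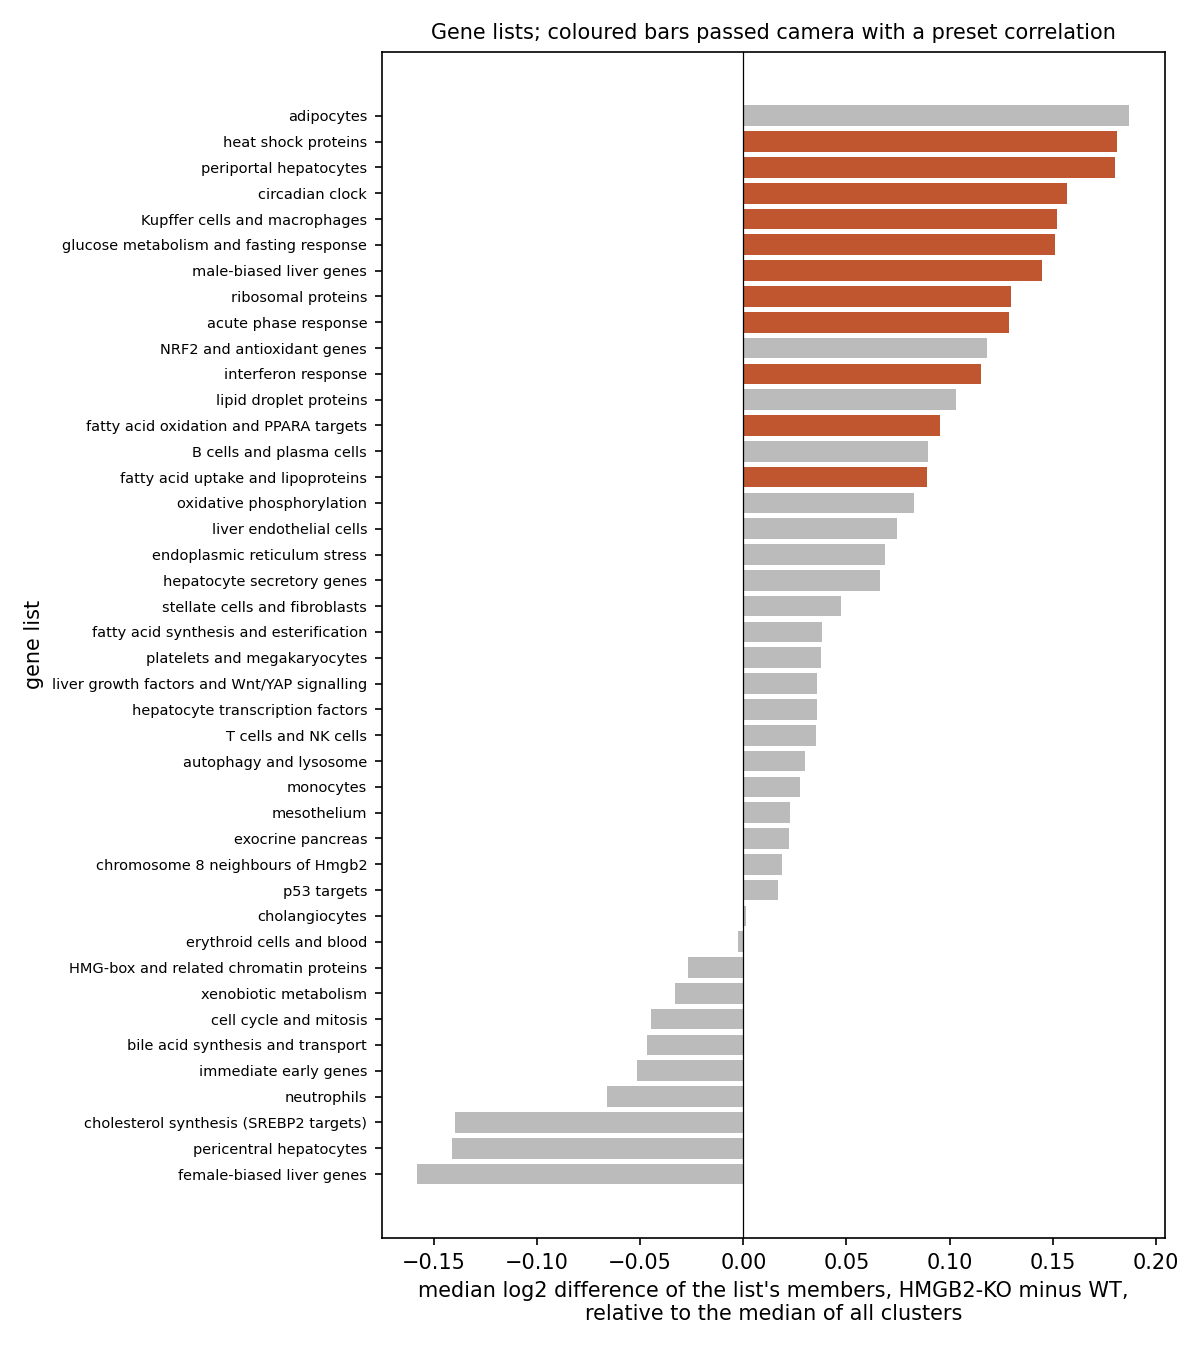
Median log2 difference of the measured members of each of the 42 gene lists (horizontal axis, HMGB2-KO minus WT, relative to the median cluster), with the lists on the vertical axis and orange bars for the 11 lists that passed camera at a preset correlation. The orange bars lie between 0.09 and 0.18, and the lowest median is -0.16, for female-biased liver genes.

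Cell cycle and mitosis genes had 22 of 36 members below the median cluster (median -0.04, camera adjusted p 0.12). The list passed as lower with quantile normalization (adjusted p 1.33e-06) and without WT replicate 1 (0.0134) or WT replicate 2 (0.0277), and had an adjusted p of 0.96 with an estimated correlation. Besides Kif11, which was the 1 member past the threshold adjusted over the list alone, Cdc6, which loads the replicative helicase, differed by -0.24 (SE 0.13) and Top2a, a topoisomerase of dividing cells, by -0.21 (SE 0.13), or -0.12 without WT replicate 3 and -0.32 with quantile normalization. In the other 41 lists, 0 members passed in limma adjusted over the list alone, and over all clusters 0 members passed in any of the 42. The adjustment over a list alone was not corrected for the 42 lists, so 1 such member may arise by chance.

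HMG-box and related chromatin proteins had 7 of 17 members above the median cluster and 10 below (median -0.03, camera adjusted p 0.894). The list is wider than the family of Hmgb2, since it was written to hold Hmgn, Hmga and histone genes too. Hmgn2, a nucleosome-binding protein, differed by -0.33 (SE 0.24), with values from -0.55 without HMGB2-KO replicate 1 to -0.14 without HMGB2-KO replicate 2. Chromosome 8 neighbours of Hmgb2, which can keep the DNA of the embryonic stem cell donor in a knockout line, had 10 of 17 members above and 7 below (median 0.02, adjusted p 0.649). The 3 with an unadjusted p under 0.05 in limma were all lower, as were 1076 of the 1092 such clusters among all genes (98.5%). Those p-values belong to the deposited differences, each 0.12 below the value given here. These 3 were Galnt7 at -0.27 (SE 0.13), Adam29 at -0.72 (SE 0.32), or -0.41 without WT replicate 2 or with array weights, and Aga at -0.25 (SE 0.16), or -0.15 without HMGB2-KO replicate 2.

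Xenobiotic metabolism had 23 of 39 members below the median cluster (median -0.03, camera adjusted p 0.649), with Gstm2, a glutathione transferase, at -0.52 (SE 0.14) and Cyp2c54 at -0.56 (SE 0.17). Bile acid synthesis and transport had 15 of 25 below it (median -0.05, adjusted p 0.743), with Slco1a4, an organic anion transporter, at -0.76 (SE 0.29). Female-biased liver genes had 20 of 25 below it (median -0.16, adjusted p 0.173), with Sult3a1, a sulfotransferase, at -0.52 (SE 0.23). The female-biased list passed as lower with centred arrays (adjusted p 0.035), quantile normalization (0.0346) and array weights (0.0322), and without WT replicate 3 (0.00374) or HMGB2-KO replicate 2 (0.0367). With an estimated correlation its adjusted p was 0.96.

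Leaving out HMGB2-KO replicate 2 placed cholesterol synthesis above the other clusters (adjusted p 9.41e-05) and leaving out HMGB2-KO replicate 3 placed it below (2.41e-08). With an estimated correlation and all samples, camera gave this list, fatty acid synthesis and xenobiotic metabolism an adjusted p of 0.96 each. Without HMGB2-KO replicate 2, fatty acid synthesis passed as higher (0.00249) and xenobiotic metabolism as lower (0.00775).

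The remaining pathway lists did not pass camera with all samples. The adjusted p was 0.959 for p53 targets, 0.211 for endoplasmic reticulum stress, 0.337 for NRF2 and antioxidant genes and 0.0952 for oxidative phosphorylation. It was 0.505 for autophagy and lysosome, 0.917 for immediate early genes, 0.649 for liver growth factors and Wnt/YAP signalling and 0.3 for hepatocyte transcription factors. Among cell types, liver endothelial cells and adipocytes each had an adjusted p of 0.0549, with medians of 0.07 and 0.19. Hepatocyte secretory genes had 0.482 and pericentral hepatocytes 0.623, the latter with a median of -0.14 and a mean of 0.04. Cholangiocytes had an adjusted p of 0.917, stellate cells and fibroblasts 0.649, monocytes 0.917, neutrophils 0.743, T cells and NK cells 0.3, and B cells and plasma cells 0.622. Erythroid cells and blood had 0.911, platelets and megakaryocytes 0.894, exocrine pancreas 0.57 and mesothelium 0.337. Some lists passed under other settings, although with an estimated correlation and all samples camera gave an adjusted p of 0.914 for oxidative phosphorylation and adipocytes and 0.96 for endothelial cells, pericentral hepatocytes, NRF2 and antioxidant genes and endoplasmic reticulum stress. Oxidative phosphorylation and liver endothelial cells passed as higher with centred arrays (adjusted p 0.0197 and 0.0375) and with quantile normalization (0.0286 each), and pericentral hepatocytes passed as lower with array weights (0.0337). Endothelial cells also passed as higher with array weights (0.0322), among clusters with a mean value above the median (0.0473) and without HMGB2-KO replicate 2 (0.0112). With a replicate block, endothelial cells (0.0416) and adipocytes passed as higher. With the block on centred arrays, endothelial cells kept their call (0.0478) and adipocytes lost theirs. With 1 sample left out, oxidative phosphorylation (0.00975) and NRF2 and antioxidant genes (0.0482) passed as higher without WT replicate 3. Endoplasmic reticulum stress did so without WT replicate 1 (0.00198) or HMGB2-KO replicate 1 (0.0218), and adipocytes without WT replicate 1 (0.0389) or HMGB2-KO replicate 3 (0.0326). The median and the mean also differed in sign for p53 targets (0.02 and -0.01), monocytes (0.03 and -0.03), cholangiocytes (0.00153 and -0.00205), erythroid cells and blood (-0.0026 and 0.06) and exocrine pancreas (0.02 and -0.04).

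**Figure D3:**
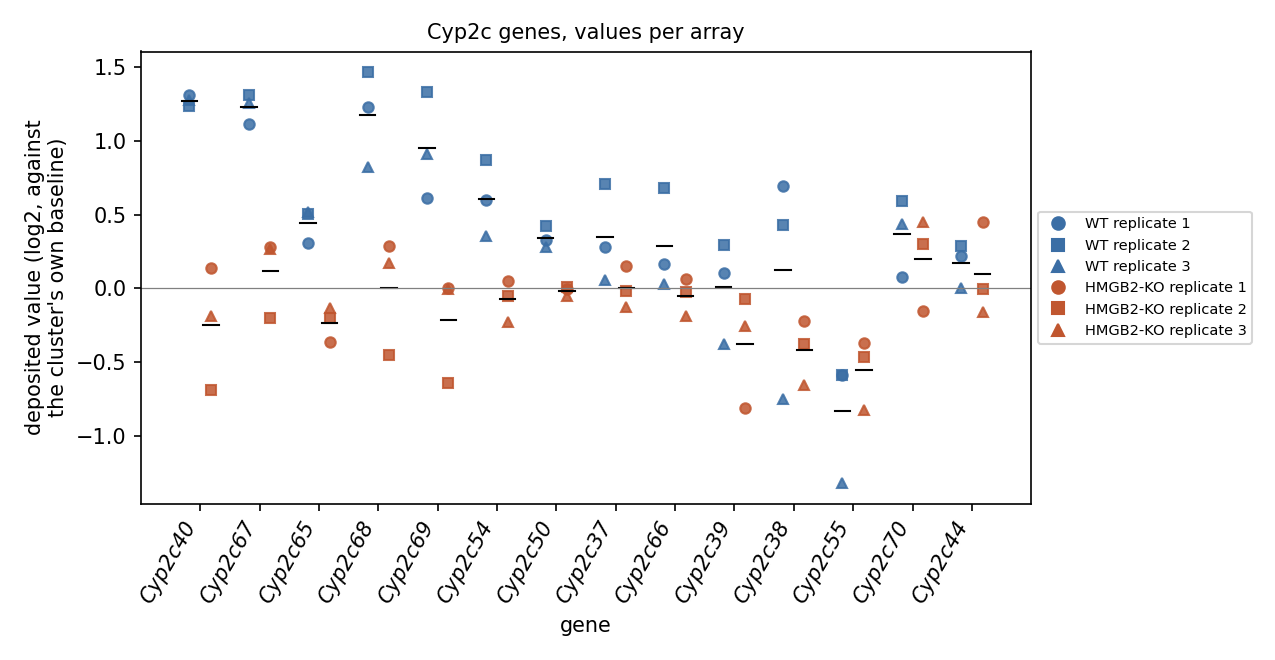
Deposited log2 values (vertical axis, against each cluster's own baseline) of the 14 measured Cyp2c genes (horizontal axis, ordered by p), a family picked after its values were seen, with WT in blue, HMGB2-KO in orange and a black line at each group mean. WT and HMGB2-KO values do not overlap in Cyp2c40, where WT lies between 1.23 and 1.31.

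**Figure D4:**
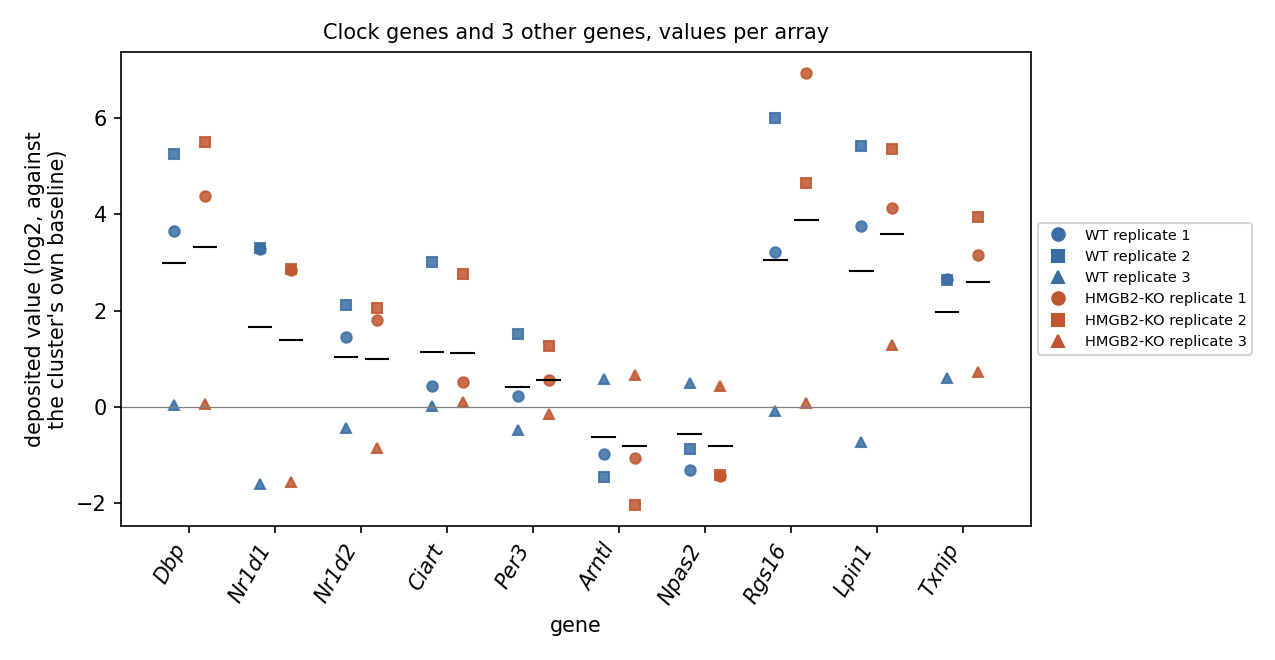
Deposited log2 values (vertical axis, against each cluster's own baseline) of 7 clock genes and of Rgs16, Lpin1 and Txnip (horizontal axis), picked after their values were seen, with WT in blue, HMGB2-KO in orange, a marker shape per replicate number and a black line at each group mean. Nr1d1 lies at 3.28, 3.29 and -1.61 in the 3 WT livers and at 2.84, 2.86 and -1.56 in the 3 HMGB2-KO livers.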

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

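The settings with WT replicate 2 left out and arrays centred, isolated low values set to missing, a replicate block on centred arrays, and lists without receptor clusters were chosen after seeing the data. The count of 0 changed genes held under every setting run except array weights, which called 6. Array weights also gave 2958 clusters at an unadjusted p under 0.05 (458 higher, 2500 lower) and 133 under the looser 2-fold rule (63 higher, 70 lower), against 1092 (16 and 1076) and 68 (3 and 65). Filters on the mean value left 11103 or 5552 clusters, and gave 521 or 221 at the unadjusted p, 19 or 16 under the 2-fold rule, and for the stricter filter 6 lists; fewer clusters and lists were tested there. These filters do not remove dim clusters, since the values are centred. The 2-fold count was 40 with centred arrays and 30 with the ordinary test. With WT replicate 2 left out and arrays centred, 723 clusters (308 higher, 415 lower), 41 under the 2-fold rule (16 and 25) and 2 lists were found. With the correlation estimated, 0 lists passed, and with fry 0. Under fry, which does not compare a list with other genes, 5 lists turned to lower: fatty acid uptake and lipoproteins (adjusted p 0.777), and fatty acid oxidation, interferon response, ribosomal proteins and periportal hepatocytes (0.989 each). Fry was run on deposited values, where the median cluster itself lay at -0.124. Why these settings gave other results was not tested, apart from the checks on the 11 lists given further below. Leaving out 1 sample gave 720 (without HMGB2-KO replicate 2) to 2125 (without WT replicate 3) clusters at the unadjusted p, 42 (without WT replicate 2) to 181 (without WT replicate 3) under the 2-fold rule, and 3 (without WT replicate 2) to 13 (without HMGB2-KO replicate 2) lists. It turned the direction of 4 named list members, none past the threshold: Apcs (-0.57 to 0.153), Ldah (-0.228 to 0.0292), Acss2 (-0.592 to 0.0432) and Fads1 (-0.316 to 0.0631). Hmgb2 stayed lower in the 16 alternatives that kept it, from -0.959 to -0.797, with adjusted p from 0.0751 to 0.992. Of 1338 other values of 79 named genes, 1332 kept direction and side of the threshold, and Rgs21 passed with array weights (adjusted p 0.0404). Several alternatives could not move a difference. The other deposited table was identical, and the block, the trended robust variance and the ordinary test left Hmgb2 at -0.885. The smallest limma adjusted p as deposited was 0.403, so keeping the side of the threshold says little. The replicate block gave 0 changed genes, 1273 clusters at the unadjusted p, 85 under the 2-fold rule and 14 lists, adding lipid droplet proteins, liver endothelial cells and adipocytes (adjusted p 0.0416 each) to the 11; with an estimated correlation and no block these had 0.96, 0.96 and 0.914, and with the block on centred arrays 0.0569, 0.0478 and 0.214, while the clock (0.0501) and periportal (0.102) lists no longer passed. Same-numbered samples deviated together with correlations of 0.016, 0.134 and 0.275 across genes, and the design names no pairing, so the numbers were not taken as pairs. A correlation over all clusters cannot show that the samples are unpaired. Of the 6 samples, 5 correlated best with their own number, a hint from the data and not from the design. With the block the SE of the clock gene Nr1d1 fell from 1.60 to 0.172, and its limma adjusted p was 0.796.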

Other observations

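The genes in these 2 paragraphs on biology were chosen after their values were seen, and so were the tests that follow, except those of an array batch and of other splits of the samples. Some of the widest spreads lay between samples of one genotype. Rgs16, a regulator of G protein signalling, had values of 3.21, 6.00 and -0.09 in WT and 6.93, 4.64 and 0.09 in HMGB2-KO, and its within-group SD of 3.27 ranked 1 among all clusters. The metallothionein gene Mt2 had -4.47, -0.16 and -6.41 in WT and -0.32, -1.74 and -6.66 in HMGB2-KO. Saa1, an acute phase protein, had -4.94, -4.01 and -2.53 in WT and -4.74, -4.09 and -0.48 in HMGB2-KO.

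Mki67 and Ube2c, 2 genes of dividing cells, lay below the baseline in all 6 livers. Mki67 ran from -2.67 to -2.14 in WT and from -2.89 to -2.78 in HMGB2-KO. Ube2c ran from -3.53 to -2.60 in WT and from -3.52 to -3.09 in HMGB2-KO. The arrays that set the baseline were not analysed here.

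Most clusters had lower values in HMGB2-KO, and 11 lists stood above the rest. Without WT replicate 2 the median difference was -0.0397, and the HMGB2-KO mean lay within 0.1 of WT replicate 3 (-0.00664), so most of the shift came with the raised values of the WT replicate 2 array. That rise was not one offset for all clusters. Relative to each array's own median, the median receptor cluster lay at 0.284 in WT replicate 2 and from -0.0671 to 0.00275 in the other 5 arrays. With centred arrays the median difference of receptor clusters between HMGB2-KO and WT was still -0.147. Lower signal in every HMGB2-KO liver stays open, since the normalization is not known and may have set the other 5 medians to one level. Of the 11 lists, 2 stayed called without WT replicate 2, so that array may contribute. With the correlation estimated per list 0 stayed called. Camera then also rests on the residual degrees of freedom of 6 arrays, so that loss cannot show that members vary together. In fatty acid uptake the estimated correlation was only 0.033, yet the camera p rose from 0.00597 to 0.0879. The estimates for the 11 lists ran from 0.033 to 0.48, above the preset 0.01, so joint variation between samples may contribute too. WT replicate 2 also held 132 values more than 2 below all 5 other arrays, against 33 in WT replicate 1 and 4 to 6 in the other 4, among them Apoa2 (-7.00) and Top1 (-8.60). A change of these lists in HMGB2-KO stays open and untested beyond this.

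Clock genes differed between samples of one genotype and matched between samples of one number. Nr1d1, a repressor in the clock, was 3.28, 3.29 and -1.61 in WT and 2.84, 2.86 and -1.56 in HMGB2-KO, and Arntl, an activator that it represses, was -0.98, -1.46 and 0.57 against -1.07, -2.03 and 0.67. Over the 21 clock genes the lowest same-number correlation of deviations was 0.93, against at most 0.535 between other numbers, across genes that are not independent. The match was not confined to the clock: in 8 of 42 lists, this one included, all 6 samples correlated best with their own number, and in 4 lists none did. The lowest same-number correlation was 0.666 in male-biased genes, 0.589 in fatty acid synthesis, 0.437 in hepatocyte secretory genes, 0.18 in female-biased genes, 0.153 in adipocytes, 0.136 in growth factors and Wnt/YAP signalling and 0.127 in the interferon response. A condition shared by the samples of one number, such as the hour of sampling, may account for this, but no label gives one. In 1448 receptor clusters, taken as silent in liver, the lowest same-number correlation was 0.0308 and the highest 0.101, so the lowest lay between the bounds set for and against an array batch shared by number. Silent clusters cannot exclude one. Over all clusters the same-number correlations were 0.016, 0.134 and 0.275, against 0.93 to 0.967 in the clock list. That gap argues against an array batch as the whole account of the clock match. A batch that adds to it stays open, since 5 of the 6 samples correlated best with their own number over all clusters.

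Several Cyp2c genes, a cluster of cytochrome P450 genes on 1 chromosome, had lower values in HMGB2-KO: 12 of 14 lay below the median cluster and 7 had an unadjusted p under 0.05, while 0 passed after adjustment in limma, and Cyp2c55 (0.40, SE 0.24) and Cyp2c44 (0.05, SE 0.19) lay above it. The family median was -0.34, and -0.33 with quantile normalization. With arrays centred and without WT replicate 2 it was -0.327, which argues against that array as the whole cause, and the 40 flanking genes had a median of 0.0518, which argues against a shift of the whole chromosome segment. Fewer female-biased transcripts stay open: that list had an adjusted p of 0.173 as deposited, 0.035 with centred arrays, 0.0346 with quantile normalization and 0.0322 with array weights, all as lower, and 0.96 with an estimated correlation. Near-identical members may share probe signal, which was not tested, so single members are uncertain.

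The 6 samples allow 10 splits of 3 against 3, too few for a share under 0.05. For changed genes the real count was 0, which every one of the 10 splits must reach, so that count decides nothing, and the highest other was 2. For the 2-fold rule, 4 of 10 splits gave at least the real 68, and the highest other was 143. For lists, 2 of 10 splits gave 11 or more, and the highest other was 11.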
